A study of Mus musculus with 12 samples.

How the data were processed

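RNA was sequenced from 12 mouse libraries, 3 each of MEF, Stage1, Stage2 and iPSC. Per the labels' protocols, RNA was isolated with the miRNeasy Mini kit and made into Illumina libraries. The deposited files hold raw HTSeq counts per gene symbol, whole reads without normalisation. Per the submitters' processing notes, reads were aligned to mm10 with TopHat2 2.0.9 and Bowtie2 2.2.6, handled with SAMtools 0.1.19, counted with HTSeq 0.5.4p3 and tested with DESeq2 1.12.4. The library's strandedness and the version of the gene annotation were not given in the sources used here, so antisense pairs such as Xist and Tsix cannot be read apart with certainty.

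The files list 23420 genes, of which 804 had no count in any library. The summary lines of HTSeq stayed out of all tests. Reads outside genes made up 9.21% ± 0.304 of reads in MEF (SD, n = 3), 42.8% ± 4.11 at Stage1, 49.9% ± 3.16 at Stage2 and 38.8% ± 4.87 in iPSC. Gene totals ranged from 8916223 to 19011944. A floor of 3 counts bounds a gene without counts, per library for depth and over the 3 libraries of a group for folds. For a group total of 1 to 3 counts, the ratio is given with its 95% counting interval.

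Groups were taken from the titles, because the title carries the replicate number and the name of the deposited counts. The stage among the characteristics names another group for every library, and the naming from the characteristics was run as an alternative. The per-library marker label (unsorted or Oct4-GFP-positive) moves with that conflict, so the sorting status is given from the series text.

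All 4 groups entered a single fit in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and statmod 1.5.0. Genes were kept by filterByExpr by group, which left 14770, and scaled by TMM. A robust quasi-likelihood fit with a term for each group gave each contrast, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The common biological coefficient of variation of the fit was 0.190. Levels are TMM-scaled CPM as mean ± SD of 3 libraries. Log2 fold changes come from the fit at its default prior count. The standard error (SE) beside them was computed from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. A prior count of 2 entered the log2 CPM used for progress, principal components and correlations. Values in the plot of marker genes, and levels of single libraries in the text, are CPM of gene totals without TMM. Comparisons were Stage1 against MEF, Stage2 against Stage1, and iPSC against each of the others. Genes outside both end points had to be called at least 2-fold away from MEF and from iPSC in the same direction. Progress between MEF and iPSC was taken over genes at least 4-fold apart.

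The 32 gene lists and the rule for named genes were fixed before the data were examined, as were the tests and most of the other settings. The rule names, per comparison and direction, the 10 called genes with the largest fold change, a mean of at least 5 CPM in the higher group, no overlap between the libraries of the groups and a symbol that is not a clone, predicted or small RNA name. It names 8 genes per direction for those outside both end points, and allows any list member and the reprogramming factors. Which list members were quoted as examples was chosen after their values were seen. Y-linked Uba1y, the nuclear RNA Malat1, and the abundant MEF transcripts Lgals1, S100a11, Col12a1 and Loxl2, were also chosen after their values were seen. Lists were tested with limma's camera with an inter-gene correlation of 0.01, and adjusted by Benjamini-Hochberg over 160 tests. Of these, 62 passed 0.05, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.129. The same test counted over each list's own members is given as adjusted over the list alone. Positions are mm10 gene spans.

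The procedure was tested on simulated data with 200 changed genes for each comparison, and a further 20 genes changed 1.3-fold. Counts were drawn with the depths of the libraries and the spread per gene of the single fit over all 4 groups, not of each comparison. It recovered 64% of genes changed 2-fold and 84% of those changed 4-fold for Stage1 against MEF. The recoveries were 70% and 90% for Stage2 against Stage1, 68% and 92% for iPSC against Stage2, 42% and 88% for iPSC against Stage1, and 64% and 76% for iPSC against MEF. Of the genes called, 6.06%, 4.79%, 6.76%, 2.44% and 6.57% were unchanged ones, in the same order. These shares need not hold in the data, where far more genes were called, such as 11870 for Stage1 against MEF.

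Other settings fixed then were RLE scaling, no filter, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, fits of only the groups compared, a fold threshold of 2, replicate numbers as a block, a prior count of 0.5, other list tests, group names from the characteristics and leaving out each library. Added after seeing the data were library totals in place of TMM, leaving out 798 structural RNA genes, a minimum of 5 CPM, and the share of reads outside genes as a covariate. The fit with that covariate left out the MEF libraries.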

Results

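RNA from 4 groups of mouse cells was sequenced as 12 libraries, 3 per group. The groups follow the reprogramming of mouse embryonic fibroblasts (MEF) into induced pluripotent stem cells (iPSC). Stage1 cells were taken at day 6, and Stage2 cells 4 days after that. Per the series text, all cells other than MEF were sorted for Oct4-GFP, a green fluorescent reporter of the pluripotency gene Pou5f1 (also called Oct4). The strain label was a mixed C57BL/6 and 129 background. Reads counted on genes numbered 8916223, 18170775 and 19011944 in MEF replicates 1, 2 and 3, and 14395538, 11676480 and 12282338 at Stage1. They numbered 9257487, 12586394 and 13528952 at Stage2 and 11248584, 14074413 and 10994289 in iPSC. A count of 0 in a library allowed up to 0.158 to 0.336 CPM (counts per 1e+06 gene counts), computed as 3 counts of that library's total. Such floors and all counting intervals cover counting error only.

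The labels of each library contradicted each other. The title and the stage given among the sample characteristics named different groups in 12 of 12 libraries, with Stage1-titled libraries described as MEF, Stage2-titled as Stage1, iPSC-titled as Stage2 and MEF-titled as iPSC. Groups were taken from the titles. In all 12 libraries the mean level of the fibroblast list was above that of the pluripotency list exactly where the title said MEF. Col1a1, a fibroblast collagen, lay between 1919 and 2959 CPM in the MEF libraries and between 1.22 and 30.8 CPM in the other 9. Pou5f1 lay between 0.785 and 3.25 CPM in the MEF libraries and between 446 and 776 CPM in the others. These markers set MEF apart, and they do not order Stage1, Stage2 and iPSC, whose names rest on the titles alone.

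**Figure D1:**
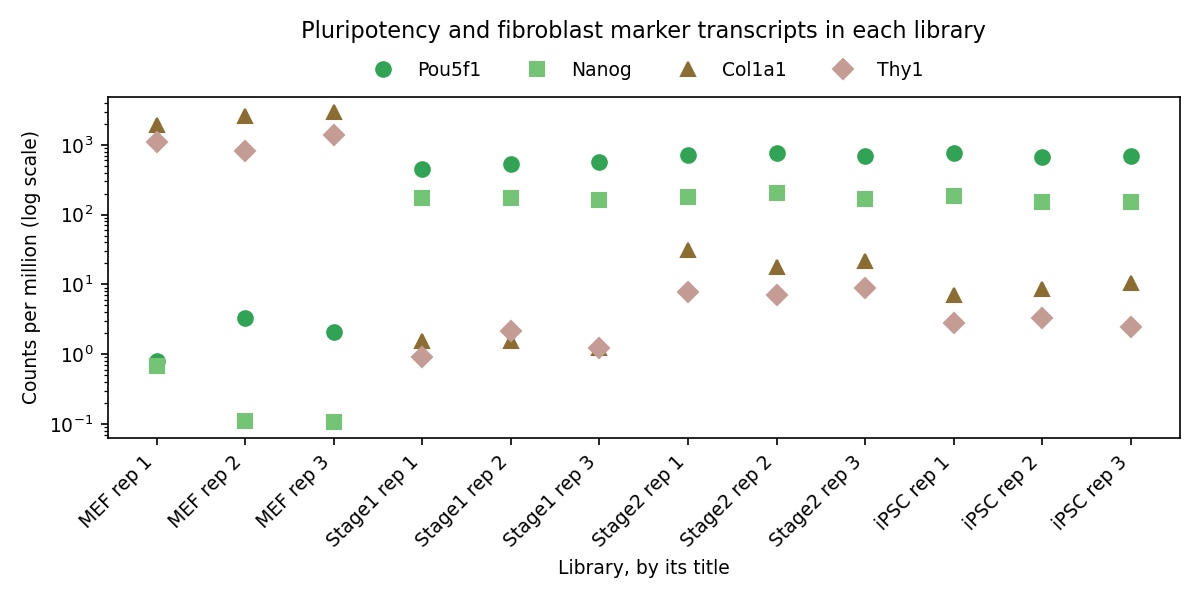
Levels of marker genes (CPM of gene counts, log axis) in each of the 12 libraries, grouped by title. Col1a1 is at least 1919 CPM in the 3 MEF libraries and at most 30.8 CPM in the other 9, where Pou5f1 is at least 446 CPM.

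The first principal component held 78.4% of the variance and set MEF apart from the other 3 groups, and the second held 10.9%. Spearman correlations across genes (which are not independent replicates) were 0.973 to 0.991 within groups. They were 0.631 to 0.666 between MEF and the other groups, 0.935 to 0.945 between Stage1 and Stage2, 0.928 to 0.939 between Stage1 and iPSC and 0.962 to 0.975 between Stage2 and iPSC. Whether the replicates came from separate animals or cultures was not given in the sources used here, so all p-values measure the spread between these libraries. The MEF group was mixed in its sex-linked transcripts. Replicate 1 had 203 CPM of Xist and 0.673 CPM of the Y-linked gene Ddx3y. Replicates 2 and 3 had 0.220 and 0 CPM of Xist and 104.3 and 111.1 CPM of Ddx3y. No batch was given, and MEF differed from the other groups in sorting as well as in cell state. The MEF libraries also differed in composition. Structural RNA genes, such as Rn45s and Rpph1, held 7.70% ± 4.52 of gene counts in MEF (SD, n = 3). They held 1.22% ± 0.265 at Stage1, 1.57% ± 0.640 at Stage2 and 1.71% ± 0.432 in iPSC.

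**Figure D2:**
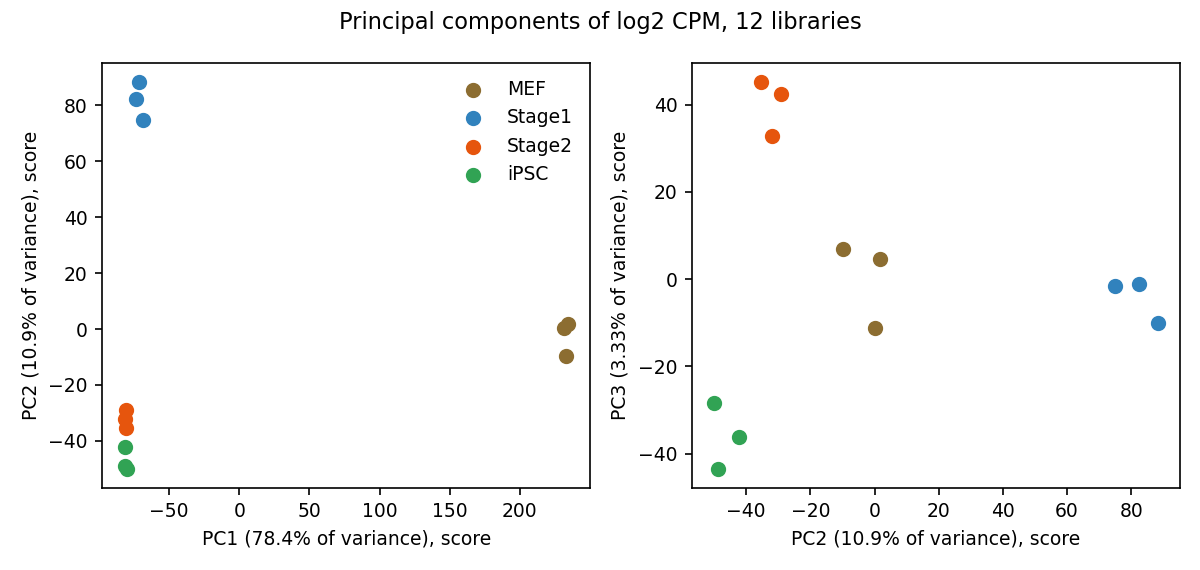
The 12 libraries on the first and second principal components of log2 CPM (percent of variance on each axis), coloured by group. The MEF libraries lie apart from the other 9 on the first component, which holds 78.4% of the variance.

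Stage1 against MEF asked what separates Oct4-GFP-positive cells at day 6 from embryonic fibroblasts. Mouse embryonic fibroblasts are mesenchymal cells that build collagen matrix and actin stress fibres. During reprogramming, cells lose this programme, take on epithelial junctions, divide faster and switch on the pluripotency network around Pou5f1, Nanog and Sox2. Of 14770 genes tested, 6533 were higher at Stage1 and 5337 were lower, and 5271 and 4308 of these differed at least 2-fold. In each leading gene named here and in the later comparisons, the 3 libraries of one group lay above the 3 of the other without overlap. The naming rule required this, so it is no separate result, and chance gives it to 10% of genes with 3 against 3.

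The fibroblast and mesenchymal list fell as a whole. All 27 members were lower at Stage1, 0 were higher and 0 were not called, and the counts adjusted over the list alone were the same. Limma's camera test with Benjamini-Hochberg adjustment gave adjusted p = 5.5e-14, and adjusted p = 0.153 with an estimated correlation. Acta2, the smooth muscle actin of stress fibres (chromosome 19, 34241090 to 34255590, mm10), averaged 12400 ± 738 CPM in MEF (SD, n = 3) and 3.42 ± 1.49 CPM at Stage1. Col1a1 (chromosome 11, 94936224 to 94953042) fell from 2897 ± 663 to 1.46 ± 0.181 CPM, a log2 fold change of -10.94 ± 0.317 (SE). Postn, a matrix protein of mesenchymal tissue, had a log2 fold change of -12.49 ± 0.393. Bgn, Actg2, Tagln, Fibin, Mfap4, Sprr2k and the G protein subunit gene Gng11 also stood among the 10 leading falls. For Gng11, counted 1 time in all Stage1 libraries together, the ratio was 10400 with a 95% counting interval of 1870 to 411000. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave these 10 genes adjusted p-values between 1.01e-14 and 1.88e-09. Fn1 and Zeb1 kept more of their level, at 440 ± 163 CPM and 9.84 CPM at Stage1 against 7082 ± 541 CPM and 77.4 CPM in MEF.

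All 18 general pluripotency genes were higher at Stage1 (18 over the list alone), with 0 lower and 0 not called, by camera with Benjamini-Hochberg adjusted p = 8.81e-07 and adjusted p = 0.153 with an estimated correlation. All 16 naive pluripotency genes were higher too (16 over the list alone), at camera adjusted p = 5.88e-05 with Benjamini-Hochberg, and adjusted p = 0.261 with an estimated correlation. Pou5f1 (chromosome 17, 35506018 to 35510772) averaged 530.2 ± 76.0 CPM against 2.41 ± 1.53 CPM in MEF, and Nanog 174.6 ± 7.88 CPM against 0.335 CPM. Lin28a, which binds let-7 microRNA precursors (chromosome 4, 134003330 to 134018841), had no count in MEF and was at least 1650-fold higher at Stage1. Fbxo15, a target of Oct4 and Sox2 (chromosome 18, 84934782 to 84981473), was at least 2350-fold higher. Such bounds set the absent group at 3 counts over its 3 libraries. Tfap2c (at least 1570-fold), Nr5a2 (at least 1280-fold), St14 (at least 1050-fold), Fam25c (at least 915-fold), Nr0b1 (at least 878-fold), Trap1a (at least 798-fold) and Calcoco2 (at least 690-fold) were likewise without a count in MEF. Tdh, the threonine dehydrogenase of mouse pluripotent cells, had a ratio of 12800 with a 95% counting interval of 3540 to 106000. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave the 10 leading genes adjusted p-values from 7.09e-15 to 4.51e-10. Klf4 rose from 17.9 ± 10 to 162.1 ± 7.86 CPM. Whether reads of Pou5f1, Sox2, Klf4 and Myc include introduced copies was not given in the sources used here.

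All 16 epithelial genes rose (16 over the list alone), at camera adjusted p = 0.000224 with Benjamini-Hochberg, and adjusted p = 0.261 with an estimated correlation. The junction genes Cdh1 and Epcam averaged 387.9 ± 7.58 and 308.9 ± 6.21 CPM at Stage1 against 0.467 and 0.144 CPM in MEF. Of 20 mitosis genes 20 were higher, and of 20 S phase genes 19 were higher and 1 was not called, the same counts as over each list alone. Camera with Benjamini-Hochberg gave adjusted p = 6.63e-09 and 1.14e-07, and adjusted p = 0.222 and 0.129 with an estimated correlation. The proliferation marker Mki67 rose from 81.9 ± 17.9 to 1283 ± 19.8 CPM. Among 18 CDK inhibitors and p53 targets, 12 were lower, 3 higher and 3 not called, also over the list alone, at camera adjusted p = 0.0230 with Benjamini-Hochberg and adjusted p = 0.219 with an estimated correlation. Cdkn1a (p21) fell from 237.7 ± 92.0 to 15.3 ± 1.66 CPM, and Cdkn2b from 110.1 ± 2.43 to 1.48 CPM.

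Of 12 TGF-beta targets 11 were lower and 1 was not called (11 over the list alone), at camera adjusted p = 3.79e-05 with Benjamini-Hochberg and adjusted p = 0.142 with an estimated correlation. The haematopoietic and macrophage list had 9 of 11 members lower and 2 not called (9 over the list alone), at camera adjusted p = 0.00917 with Benjamini-Hochberg and adjusted p = 0.222 with an estimated correlation. Its most abundant examples included Lyz2, a lysozyme of macrophages, at 78.5 ± 14.7 CPM in MEF and 1.299 CPM at Stage1. Of 13 stress genes 12 were lower and 1 higher (12 and 1 over the list alone), at camera adjusted p = 0.00129 with Benjamini-Hochberg and adjusted p = 0.222 with an estimated correlation. Of 13 DNA methylation genes 9 were higher, 3 lower and 1 not called (9 and 3 over the list alone), at camera adjusted p = 0.0389 with Benjamini-Hochberg and adjusted p = 0.462 with an estimated correlation. The methyltransferase gene Dnmt3b rose from 1.57 to 297.6 ± 103 CPM and the 5-methylcytosine oxidase gene Tet1 from 7.04 to 711.6 CPM. Of 18 germline genes 15 were higher, 0 lower and 3 not called (15 over the list alone), at camera adjusted p = 0.0438 with Benjamini-Hochberg and adjusted p = 0.379 with an estimated correlation. Several members were at low levels at Stage1, such as Sycp1 at 2.97 ± 1.58, Hormad1 at 2.89 ± 0.524, Stk31 at 1.57 ± 0.434 and Mov10l1 at 1.13 ± 0.334 CPM. Of 60 replication-dependent histone genes 39 were higher, 11 lower and 10 not called (39 and 11 over the list alone), at camera adjusted p = 0.0113 with Benjamini-Hochberg and adjusted p = 0.560 with an estimated correlation. Reads outside genes made up 9.21% ± 0.304 of reads in MEF and 42.8% ± 4.11 at Stage1. Sorting and cell state could not be separated in this comparison, and library-total scaling moved the median of all genes by 0.182 on the log2 scale relative to TMM scaling.

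**Figure D3:**
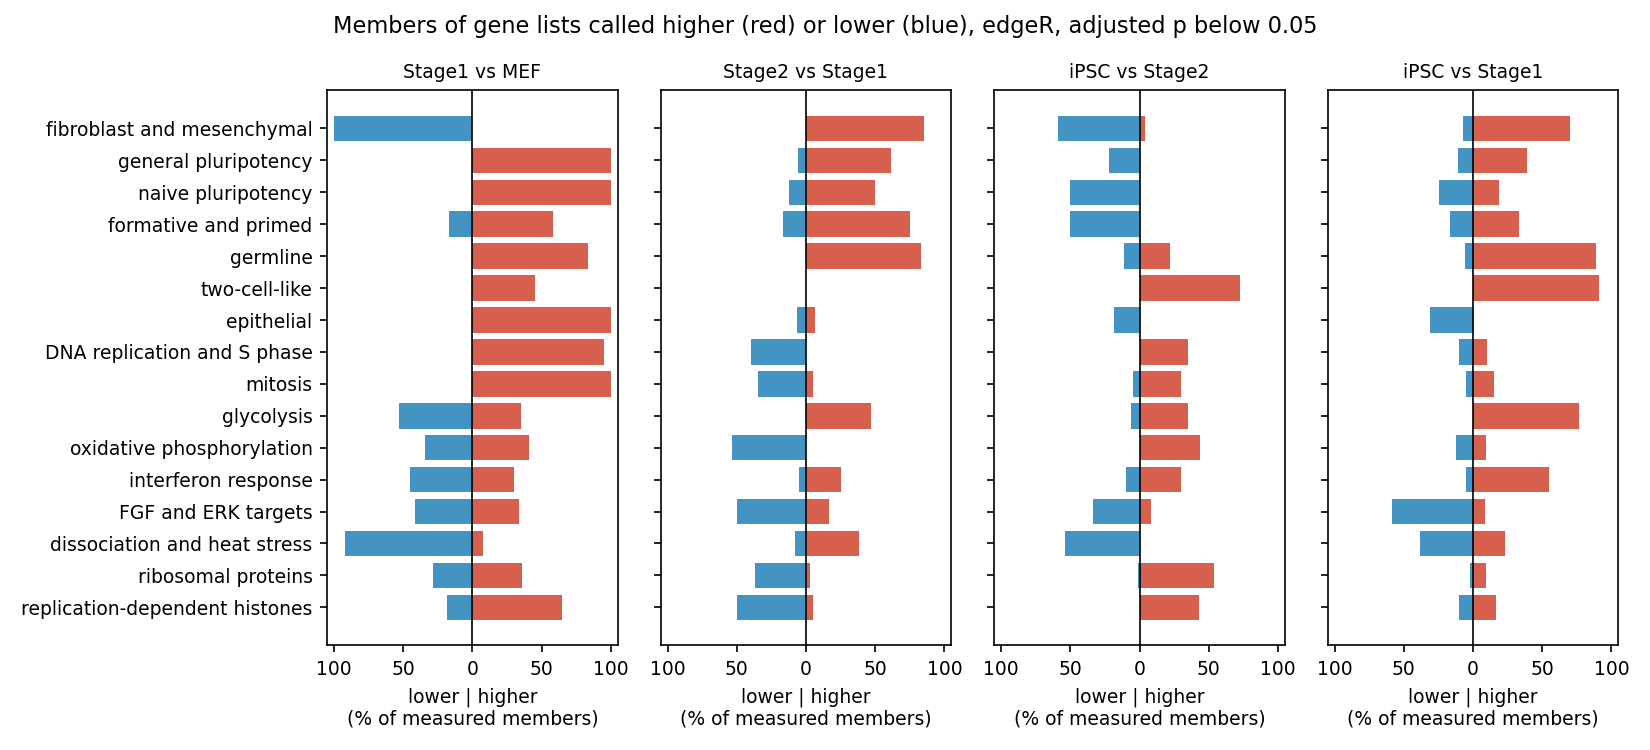
Percent of the tested members of 16 gene lists called higher (right of 0) or lower (left of 0) in each of 4 comparisons. Of 27 fibroblast genes, 27 were lower at Stage1 than in MEF and 23 were higher at Stage2 than at Stage1.

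Stage2 against Stage1 asked what changed in Oct4-GFP-positive cells over 4 further days. Pluripotent cells pass through states that differ in their markers. Naive cells resemble the inner cell mass, formative and primed cells resemble the later epiblast, and germline genes silenced by DNA methylation can be expressed where methylation is low. Of 14770 genes, 3048 were higher at Stage2 and 2921 lower, and 2193 and 774 of these differed at least 2-fold. With library totals in place of TMM scaling, the share of calls that were higher was 70.6% in place of 51.1%, with 1678 genes lower, and the median of all genes moved by 0.204 on the log2 scale, so the split between higher and lower rested on the scaling.

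Of 18 germline genes 15 were higher at Stage2 than at Stage1, 0 lower and 3 not called (16 higher over the list alone). Camera with Benjamini-Hochberg gave adjusted p = 3.01e-08, and adjusted p = 0.129 with an estimated correlation. Dazl, a germ cell RNA-binding protein (chromosome 17, 50279395 to 50293636), averaged 22.2 ± 1.94 CPM against 0.910 CPM at Stage1, a log2 fold change of 4.60 ± 0.353 (SE). Sycp3, a synaptonemal complex protein of meiosis (chromosome 10, 88459569 to 88473236), averaged 23.9 ± 3.34 against 1.48 CPM. Mael and Ddx4, of the piRNA pathway, had log2 fold changes of 4.48 and 3.32. Tuba3a, a tubulin of testis whose reads may be shared with its paralogs, had a log2 fold change of 5.89 ± 0.502.

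Of 12 formative and primed genes 9 were higher, 2 lower and 1 not called, also over the list alone, at camera adjusted p = 0.000676 with Benjamini-Hochberg and adjusted p = 0.129 with an estimated correlation. Lefty2, a secreted Nodal antagonist (chromosome 1, 180893108 to 180899103), averaged 171.6 ± 30.5 CPM at Stage2 and 3.17 CPM at Stage1. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave it a log2 fold change of 5.74 ± 0.315 and adjusted p = 5.4e-09. The epiblast genes Fgf5 (chromosome 5, 98254184 to 98277030) and Otx2 (chromosome 14, 48657677 to 48673819) reached 10.3 ± 1.49 and 55.6 ± 3.12 CPM against 0.209 and 4.65 ± 2.74 CPM. Cer1, another Nodal antagonist (chromosome 4, 82881751 to 82885148), had 3 counts at Stage1 and a ratio of 68.3 with a 95% counting interval of 23.4 to 331. Wnt8a went the other way, from 17.4 ± 6.55 to 0.714 CPM. Of 8 mesendoderm genes 5 were higher, 1 lower and 2 not called (5 and 1 over the list alone), at camera adjusted p = 0.0423 with Benjamini-Hochberg and adjusted p = 0.242 with an estimated correlation. The higher ones included the endoderm and mesoderm regulators Gsc and Foxa2, at low levels of 1.53 ± 0.0448 and 2.02 ± 0.458 CPM at Stage2. Gsc had 2 counts at Stage1, a ratio of 28.7 with a 95% counting interval of 7.96 to 237. Mixl1, Mesp1, Evx1 and Lhx1 of this list were not tested.

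Of 18 general pluripotency genes 11 were higher, 1 lower and 6 not called, also over the list alone, at camera adjusted p = 0.000118 with Benjamini-Hochberg and adjusted p = 0.222 with an estimated correlation. Library-total scaling gave 13 higher and 0 lower. Dnmt3l, the cofactor of the de novo methyltransferases (chromosome 10, 78041947 to 78063622), rose from 31.9 ± 1.68 to 302.7 ± 45.2 CPM, a log2 fold change of 3.24 ± 0.172 with adjusted p = 7.11e-10 by edgeR's quasi-likelihood test and Benjamini-Hochberg. Dppa5a rose from 170.1 ± 36.1 to 653.2 ± 75.4 CPM. Nanog and Klf4 were not called, and Nanog averaged 162.4 ± 16.9 CPM at Stage2. Pou5f1 averaged 647.1 ± 42.7 CPM and was not called, but was called higher, with a log2 fold change of 0.33, in a fit of only these 6 libraries and with 0.50 in library-total scaling. Of 16 naive genes 8 were higher, 2 lower and 6 not called (8 and 2 over the list alone), with camera adjusted p = 0.0609 with Benjamini-Hochberg. Klf5 and Tcl1 rose, with log2 fold changes of 2.78 and 1.94, and Dppa3 fell, with -1.63 ± 0.243.

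The fibroblast and mesenchymal list was higher at Stage2 than at Stage1 in 23 of 27 genes (23 over the list alone), with 0 lower and 4 not called, Twist2, Dcn and Lum among them. Camera with Benjamini-Hochberg gave adjusted p = 4.13e-09, and adjusted p = 0.222 with an estimated correlation. The levels stayed far below MEF. Col1a1 averaged 20.8 ± 6.34 CPM, Acta2 46.0 ± 13.4 CPM and the collagen crosslinking enzyme gene Lox 34.4 ± 6.53 CPM. Their log2 fold changes were 3.81 ± 0.280, 3.78 ± 0.268 and 4.18 ± 0.207. TGF-beta targets were higher in 7, lower in 3 and not called in 2 of 12 genes (7 and 3 over the list alone), at camera adjusted p = 0.0465 with Benjamini-Hochberg and adjusted p = 0.357 with an estimated correlation. The BMP target Id3 (chromosome 4, 136143497 to 136145755) fell with a log2 fold change of -3.14 ± 0.258. Myc (chromosome 15, 61985391 to 61990374) fell from 46.9 ± 4.65 to 3.73 ± 1.79 CPM.

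Of 17 glycolysis genes 8 were higher, 0 lower and 9 not called (8 over the list alone), at camera adjusted p = 0.000658 with Benjamini-Hochberg and adjusted p = 0.494 with an estimated correlation. The hexokinase gene Hk1 and the glucose transporter gene Slc2a1 rose with log2 fold changes of 1.72 and 1.53. Of 32 oxidative phosphorylation genes 17 were lower, 0 higher and 15 not called (17 over the list alone), at camera adjusted p = 7.38e-05 with Benjamini-Hochberg and adjusted p = 0.379 with an estimated correlation, and 10 were lower with library-total scaling. Cytochrome c (Cycs) fell with -1.01 ± 0.191. S phase genes were lower in 8 of 20, higher in 0 and not called in 12 (8 over the list alone), at camera adjusted p = 0.00260 with Benjamini-Hochberg and adjusted p = 0.270 with an estimated correlation, and 5 were lower and 2 higher with library-total scaling. Reads outside genes made up 49.9% ± 3.16 of reads at Stage2 and 42.8% ± 4.11 at Stage1, and the nuclear RNA Malat1 averaged 14230 ± 288 and 9707 ± 1400 CPM and was called higher, which ended without Stage1 replicate 2 or 3 (adjusted p = 0.0648 and 0.0657 in edgeR with Benjamini-Hochberg). Ribosomal protein genes were lower in 29, higher in 2 and not called in 47 of 78 (28 and 2 over the list alone), at camera adjusted p = 3.98e-06 with Benjamini-Hochberg and adjusted p = 0.537 with an estimated correlation. Only 5 were lower and 3 higher with library-total scaling, and 19 and 2 with RLE scaling. Replication-dependent histone genes, poorly captured where poly(A) is selected, were lower in 30, higher in 3 and not called in 27 of 60 (32 and 3 over the list alone), at camera adjusted p = 2.63e-05 with Benjamini-Hochberg and adjusted p = 0.379 with an estimated correlation.

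Prmt8, an arginine methyltransferase gene (chromosome 6, 127689011 to 127769472), was among the leading rises, from 0.228 to 20.98 ± 1.67 CPM. The protease inhibitor gene A2m rose from 2.05 to 148.2 ± 21.7 CPM, and Ripply1, Crtac1, Mcf2, Trim52 and Krt42 completed the 10 leading rises with Cer1, Tuba3a and Lefty2. EdgeR's quasi-likelihood test with Benjamini-Hochberg gave them adjusted p-values from 2.34e-10 to 1.67e-05. Cyp2b23, a cytochrome P450 gene (chromosome 7, 26665227 to 26686437), fell from 69.2 ± 7.33 to 2.43 ± 0.354 CPM. Foxd1, Dmrtc1b, Wnt8a, Aldh3a1, Serpinb6b, Insm1, Capn6, Htr5b and Nt5e completed the 10 leading falls, with adjusted p-values by the same edgeR test and Benjamini-Hochberg from 2.34e-10 to 0.0107. Foxd1 averaged 14.2 ± 17.5 CPM at Stage1, an SD above its mean.

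**Figure D4:**
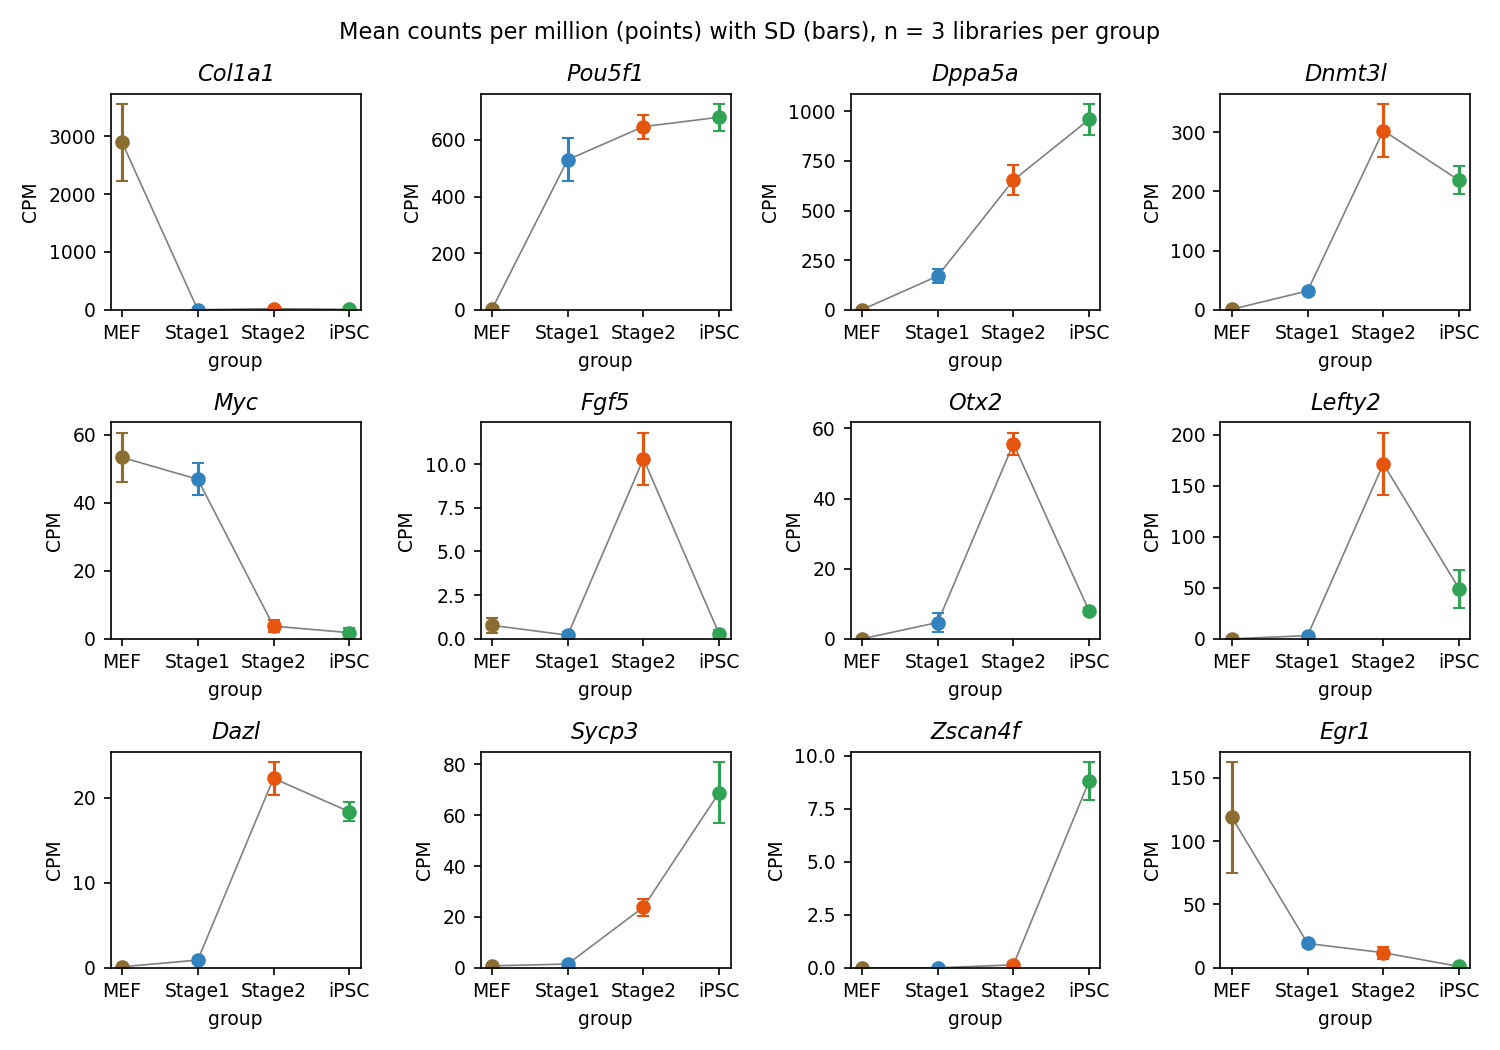
Mean level (CPM, linear axis) of 12 genes in MEF, Stage1, Stage2 and iPSC, with error bars of 1 SD over 3 libraries. Dnmt3l rises from 31.9 CPM at Stage1 to 302.7 CPM at Stage2, and Fgf5 and Otx2 are highest at Stage2.

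The comparison of iPSC with Stage2 asked how the sorted day 6 + 4 cells differ from the established pluripotent cells. Cultured mouse pluripotent cells contain a few cells that express genes of the 2-cell embryo, among them the Zscan4 cluster, which is linked to telomere upkeep. Pluripotent cells also vary in how far they express epiblast genes. Of 14770 genes, 1360 were higher in iPSC and 1310 lower, and 430 and 520 of these differed at least 2-fold. The share of calls that were higher was 50.9%, against 42.8% with RLE scaling and 34.1% with library totals. With the share of reads outside genes as a covariate, chosen after the data were seen, a fit without MEF gave 401 higher and 590 lower. That share itself differed between the groups, at 49.9% ± 3.16 of reads at Stage2 and 38.8% ± 4.87 in iPSC. Calls lost with it therefore cannot be assigned to reads outside genes. A fit of only these 6 libraries gave 2307 higher and 2647 lower. Leaving out any 1 of the 6 libraries lowered both counts by more than 1.5 times, to between 665 and 856 higher and 568 and 812 lower, for each of Stage2 replicates 1, 2 and 3 and iPSC replicates 1, 2 and 3.

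Of 11 2-cell-like genes tested 8 were higher, 0 lower and 3 not called (9 higher over the list alone), at camera adjusted p = 3.12e-08 with Benjamini-Hochberg and adjusted p = 0.129 with an estimated correlation. Zscan4f (chromosome 7, 11397915 to 11402318) averaged 8.81 ± 0.910 CPM in iPSC and 0.141 ± 0.147 CPM at Stage2, a log2 fold change of 6.01 ± 0.630 with adjusted p = 7.51e-05 by edgeR's quasi-likelihood test and Benjamini-Hochberg. Zscan4c averaged 5.14 ± 0.897 against 0.354 CPM. Zscan4d had no count at Stage2 and was at least 45.7-fold higher in iPSC. Dux, which activates this programme, was not called. Members of the Zscan4 cluster are near copies, so their reads cannot be assigned to single genes with certainty. Zscan4a averaged 7.61 ± 1.17 against 0.783 CPM, and its call ended with DESeq2 (adjusted p = 0.0608 by Benjamini-Hochberg).

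Of 12 formative and primed genes 6 were lower in iPSC, 0 higher and 6 not called (7 lower over the list alone), at camera adjusted p = 7.95e-06 with Benjamini-Hochberg and adjusted p = 0.129 with an estimated correlation. Fgf5 fell to 0.277 CPM, a log2 fold change of -5.22 ± 0.608, Otx2 to 7.92 ± 0.898 CPM, and Lefty2 to 49.2 ± 18.8 CPM. Cer1, with 3 counts in iPSC, was higher at Stage2 by a ratio of 69.3 with a 95% counting interval of 23.7 to 336. Of 8 mesendoderm genes 2 were lower, 0 higher and 6 not called (4 lower over the list alone), at camera adjusted p = 0.00203 with Benjamini-Hochberg and adjusted p = 0.153 with an estimated correlation. Of 16 naive genes 8 were lower, 0 higher and 8 not called (8 over the list alone), at camera adjusted p = 4.34e-06 with Benjamini-Hochberg and adjusted p = 0.222 with an estimated correlation. Klf5, Dppa3, Klf2 and Prdm14 fell, with log2 fold changes of -1.86, -1.37 ± 0.246, -1.09 and -0.90. Of 18 general pluripotency genes 4 were lower, 0 higher and 14 not called (5 lower over the list alone), at camera adjusted p = 0.0315 with Benjamini-Hochberg and adjusted p = 0.427 with an estimated correlation. Sall4, a zinc finger regulator of pluripotency, fell with a log2 fold change of -0.84. Of 18 germline genes 4 were higher, 2 lower and 12 not called (5 and 2 over the list alone), at camera adjusted p = 0.0400 with Benjamini-Hochberg and adjusted p = 0.379 with an estimated correlation. Tex11, Sycp3 and Ddx4 rose, with log2 fold changes of 2.48, 1.53 and 1.48, and Rhox5 fell, with -2.09. Stra8, the retinoic acid-induced gene that opens meiosis, rose from 1.87 ± 0.672 to 18.5 ± 1.15 CPM.

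The fibroblast list was lower in iPSC than at Stage2 in 16, higher in 1 and not called in 10 of 27 genes (17 and 2 over the list alone), at camera adjusted p = 8.76e-06 with Benjamini-Hochberg and adjusted p = 0.313 with an estimated correlation. Stress genes were lower in 7 and not called in 6 of 13 (7 lower and 1 higher over the list alone), at camera adjusted p = 0.0252 with Benjamini-Hochberg and adjusted p = 0.353 with an estimated correlation. The immediate early gene Egr1 (chromosome 18, 34859823 to 34864984) fell from 11.9 ± 4.64 to 1.07 ± 0.137 CPM, and Jun and Fosb fell too, with log2 fold changes of -2.23 and -3.74. Interferon response genes were higher in 6, lower in 2 and not called in 12 of 20 (6 and 2 over the list alone), at camera adjusted p = 0.0228 with Benjamini-Hochberg and adjusted p = 0.358 with an estimated correlation. Usp18 and Oas1a rose with log2 fold changes of 3.47 and 2.49, and Irf8, Ifi27l1 and Rtp4 were among the 10 leading rises. DNA methylation genes were lower in 5 and not called in 8 of 13 (5 over the list alone), at camera adjusted p = 0.0102 with Benjamini-Hochberg and adjusted p = 0.379 with an estimated correlation.

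Several lists that were lower at Stage2 than at Stage1 were higher in iPSC than at Stage2, while reads outside genes made up 38.8% ± 4.87 of reads in iPSC and 49.9% ± 3.16 at Stage2, and Malat1 averaged 8395 ± 1660 and 14230 ± 288 CPM. Ribosomal protein genes were higher in iPSC in 42, lower in 1 and not called in 35 of 78 (61 and 2 over the list alone), at camera adjusted p = 6.67e-16 with Benjamini-Hochberg and adjusted p = 0.301 with an estimated correlation. With library totals 27 were higher and 1 lower. Oxidative phosphorylation genes were higher in 14 and not called in 18 of 32 (18 over the list alone), at camera adjusted p = 1.48e-07 with Benjamini-Hochberg and adjusted p = 0.280 with an estimated correlation, and 8 were higher with library totals. Histone genes were higher in 26 and not called in 34 of 60 (33 over the list alone), at camera adjusted p = 1.86e-11 with Benjamini-Hochberg and adjusted p = 0.222 with an estimated correlation. S phase genes were higher in 7 and not called in 13 of 20 (10 over the list alone), at camera adjusted p = 3.98e-06 with Benjamini-Hochberg and adjusted p = 0.153 with an estimated correlation. Mitosis genes were higher in 6, lower in 1 and not called in 13 of 20 (8 and 2 over the list alone), at camera adjusted p = 0.0253 with Benjamini-Hochberg and adjusted p = 0.549 with an estimated correlation, and their balance turned with library totals, to 1 higher and 2 lower.

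Several Y-linked genes were lower in iPSC than at Stage2. Zfy1 (chromosome Y, 725128 to 797409) fell from 27.6 ± 3.92 to 1.29 ± 0.328 CPM and Usp9y (1298961 to 1459782) from 6.80 ± 1.57 to 0.422 ± 0.256 CPM, after 4.20 ± 1.85 and 2.91 ± 0.556 CPM at Stage1, with adjusted p = 2.3e-06 and 0.000102 by edgeR's quasi-likelihood test and Benjamini-Hochberg. The histone demethylase gene Kdm5d (897788 to 956786) averaged 79.8 ± 7.27 CPM at Stage1, 48.8 ± 2.92 CPM at Stage2 and 2.00 ± 0.271 CPM in iPSC, at adjusted p = 0.0160 by the same edgeR test with Benjamini-Hochberg. Its call ended without iPSC replicate 1, 2 or 3, at adjusted p = 0.0708, 0.0630 and 0.0573, with log2 fold changes of -4.50, -4.58 and -4.70. The libraries of Stage2 and iPSC stayed far apart for Kdm5d, at 52.4 to 59.5 and 1.87 to 2.46 CPM of gene totals. The single fit also takes its spread from the MEF libraries, where Kdm5d stood at 0.112, 24.8 and 31.5 CPM. Eif2s3y, Uty and Ddx3y, which lie between Kdm5d and Usp9y, were not called and kept 60.5%, 66.5% and 54.9% of their Stage2 level. In a fit of only these 6 libraries they were called lower, with log2 fold changes of -0.78, -0.64 and -0.92. That fit leaves out the MEF libraries, of which replicate 1 had nearly no Y-linked reads. Cox7b2, Smok4a, Slfn9, Fosb, Egr1, Cer1 and Fgf5 made up the rest of the 10 leading falls. Among the leading rises, Hist1h2aa reached 10.2 ± 1.65 CPM. Thrsp reached 5.47 ± 1.80 CPM, and its call ended without Stage2 replicate 1 (adjusted p = 0.0510) or iPSC replicate 1 (adjusted p = 0.0505) in edgeR with Benjamini-Hochberg. With the share of reads outside genes as a covariate, in the fit without MEF, the calls of Klf5, Dppa3, Lefty2, Rhox5 and Fosb ended. Their log2 fold changes were then -2.26, -1.64, -2.01, -2.25 and -3.72. The calls of Thrsp and Zscan4a ended at 2.46 and 3.41, and that of Malat1 at -0.60.

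**Figure D5:**
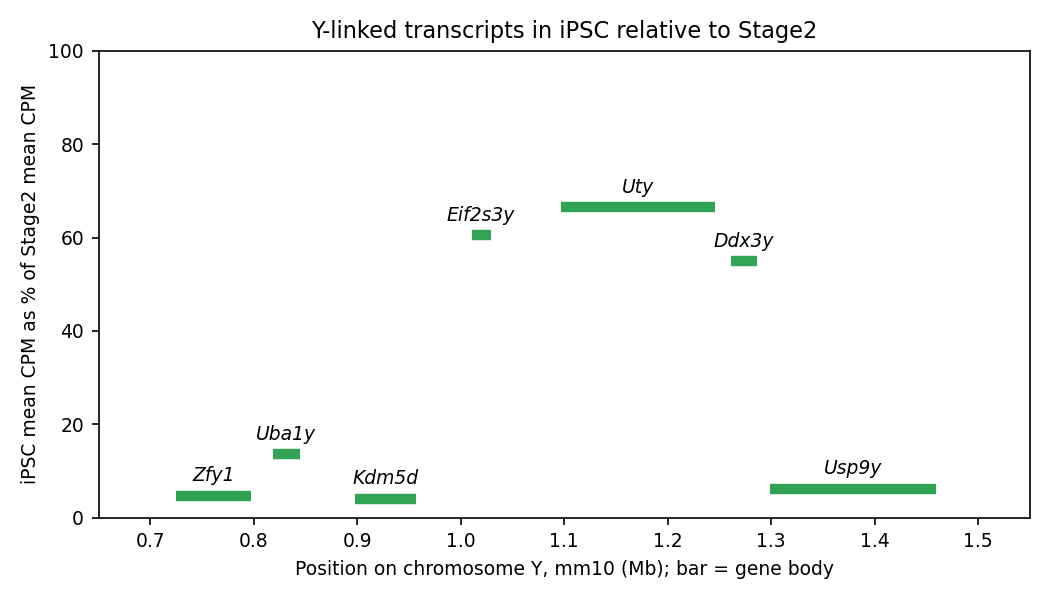
Level in iPSC as a percent of the Stage2 level for 7 Y-linked genes of at least 5 CPM at Stage2, against their position on the Y chromosome (mm10). Kdm5d keeps 4.10% and Usp9y 6.20%, and the 3 genes between them keep 54.9% to 66.5%.

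The comparison of iPSC with Stage1 asked how far the day 6 cells were from the end state. Cells at an early stage of reprogramming can express pluripotency factors before their metabolism and chromatin regulators reach the levels of established cells. Of 14770 genes, 3143 were higher in iPSC and 2677 lower, and 2278 and 857 of these differed at least 2-fold. Library totals moved the median of all genes by 0.104 on the log2 scale. Of 18 germline genes 16 were higher, 1 (Rhox5) lower and 1 not called (17 and 1 over the list alone), at camera adjusted p = 6.63e-09 with Benjamini-Hochberg and adjusted p = 0.129 with an estimated correlation. Sycp3 averaged 68.9 ± 12.1 CPM in iPSC against 1.48 CPM, a log2 fold change of 5.52 ± 0.255, and Ddx4 had 4.80. Of 11 2-cell-like genes 10 were higher and 1 not called (10 over the list alone), at camera adjusted p = 1.6e-05 with Benjamini-Hochberg and adjusted p = 0.129 with an estimated correlation, and Zscan4f, without a count at Stage1, was at least 110-fold higher. Of 17 glycolysis genes 13 were higher and 4 not called (15 over the list alone), at camera adjusted p = 1.52e-06 with Benjamini-Hochberg and adjusted p = 0.362 with an estimated correlation, with Slc2a1 at a log2 fold change of 1.96 ± 0.239. Interferon response genes were higher in 11, lower in 1 and not called in 8 of 20 (11 and 1 over the list alone), at camera adjusted p = 0.00427 with Benjamini-Hochberg and adjusted p = 0.280 with an estimated correlation.

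FGF and ERK targets were lower in iPSC than at Stage1 in 7, higher in 1 and not called in 4 of 12 (8 and 1 over the list alone), at camera adjusted p = 0.00420 with Benjamini-Hochberg and adjusted p = 0.468 with an estimated correlation. Myc and Egr1 fell with log2 fold changes of -4.64 ± 0.376 and -4.15 ± 0.342. Of 18 general pluripotency genes 7 were higher, 2 lower and 9 not called (7 and 3 over the list alone), at camera adjusted p = 0.0446 with Benjamini-Hochberg and adjusted p = 0.453 with an estimated correlation. Nanog and Esrrb were not called. Of 16 naive genes 3 were higher, 4 lower and 9 not called (3 and 4 over the list alone), with camera adjusted p = 0.302 by Benjamini-Hochberg, and Dppa3 fell from 259.7 ± 46.3 to 32.4 ± 9.89 CPM. The fibroblast list was higher in 19, lower in 2 and not called in 6 of 27 (20 and 3 over the list alone), at camera adjusted p = 9.13e-05 with Benjamini-Hochberg and adjusted p = 0.369 with an estimated correlation. The DNA methyltransferase genes moved apart, with log2 fold changes of 2.77 for Dnmt3l, 1.92 ± 0.225 for Dnmt3a and -1.54 ± 0.302 for Dnmt3b. Prmt8 and Stra8 led the rises with Zscan4f, Igsf21, Hist1h2aa, Lefty1, Myo1f, Krt42, Kcnk1 and Trim52. Prmt8 and Stra8 had log2 fold changes of 7.53 ± 0.436 and 6.07 ± 0.399. Igsf21 had a ratio of 133 (95% counting interval 36.9 to 1100). The 10 leading falls were Cyp2b23, Npy, Capn6, Foxd1, Id3, Aox3, the clock gene Arntl2, Kdm5d, Nkx1-2 and Nefm. Cyp2b23, Id3 and Arntl2 had log2 fold changes of -6.18 ± 0.261, -5.49 ± 0.319 and -5.39 ± 0.340. EdgeR's quasi-likelihood test with Benjamini-Hochberg gave the 20 genes adjusted p-values from 4.23e-11 to 0.00825.

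The comparison of iPSC with MEF set the end points of the series beside each other. Of 14770 genes, 6636 were higher in iPSC and 5294 lower, and 5408 and 4154 of these differed at least 2-fold. All 27 fibroblast genes were lower, and all 18 general pluripotency genes and 18 germline genes were higher, with the same counts over each list alone. The meiosis gene Hormad1 and the piRNA pathway gene Mael, without a count in MEF, were at least 337-fold and at least 245-fold higher in iPSC. Library totals moved the median of all genes by 0.283 on the log2 scale. Between these end points, a progress of 0% puts a gene at its MEF level and 100% at its iPSC level on the log2 scale. The 3500 genes at least 4-fold higher in iPSC had a median progress of 87.7% ± 1.51 at Stage1 (SD over 3 libraries) and 98.3% ± 0.988 at Stage2. The 2560 genes at least 4-fold lower had 100.9% ± 2.14 and 96.5% ± 0.454. Of the genes higher in iPSC, 28.6% were called at least 2-fold below their iPSC level at Stage1 and 4.63% above it. At Stage2 these shares were 5.29% and 4.69%. Of the genes lower in iPSC, 16.6% were called at least 2-fold below their iPSC level at Stage1 and 11% above it. At Stage2 these were 3.16% and 7.15%. Progress had no test, since iPSC levels enter both sides of it.

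Genes outside both end points were those called at least 2-fold above, or at least 2-fold below, both MEF and iPSC in edgeR's quasi-likelihood test. At Stage1, 403 genes were above both and 1031 below both, against 305.8 and 664.4 if the contrasts were independent. At Stage2, 264 were above and 192 below, against 188.4 and 123.7. In 5 simulations without any effect 0 genes passed, which the thresholds in both contrasts nearly ensure and which leaves out the difference between MEF and iPSC. The contrasts share the libraries of the stage, which raises the overlap by an amount that 3 libraries per group cannot separate. Leaving out 1 library changed the 264 genes above both at Stage2 to between 166 and 347, with 166 without Stage2 replicate 1 and 169 without iPSC replicate 1.

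Above both at Stage1 stood Cyp2b23 at 69.2 ± 7.33 CPM, against 0.0223 CPM in MEF and 0.950 CPM in iPSC. Nefm, a neurofilament gene, averaged 33.3 ± 7.12 CPM at Stage1, 0.0201 CPM in MEF and 0.955 CPM in iPSC. Fgfbp1, which releases fibroblast growth factors from the matrix, averaged 58.8 ± 4.42 CPM, 0.334 CPM and 2.39 CPM in the same order. Aox3, Nkx1-2, Ceacam2, Clec2i and Dmrtc1b completed the leading 8. Below both at Stage1 stood Kdelr3, an endoplasmic reticulum retention receptor gene, at 0.984 CPM, against 301.5 ± 61.0 CPM in MEF and 32.8 ± 3.41 CPM in iPSC. Aplp1, of the amyloid precursor family, averaged 0.519 CPM at Stage1, 53.5 ± 21.8 CPM in MEF and 20.8 ± 2.72 CPM in iPSC. Smarcd3, Cmklr1, Ifi27l1, Spsb1, Epb4.1l1 and the matrix gene Tgfbi completed that group. At Stage2, Cer1, Zfy1, Cox7b2, Usp9y, Fgf5, Smok4a, Slfn9 and Gdpd3 stood above both end points. Fgf5 averaged 10.3 ± 1.49 CPM at Stage2, 0.772 ± 0.421 CPM in MEF and 0.277 CPM in iPSC. Ifi27l1, Ptgr1, Gdpd1, Nenf, Gsdmd, Rpph1, Map3k6 and Hist1h3e stood below both. Rpph1 is one of the structural RNA genes, of which MEF held a larger share. It averaged 10580 ± 3570 CPM in MEF, 219.3 ± 46 CPM at Stage2 and 761.3 ± 326 CPM in iPSC. With the share of reads outside genes as a covariate, in the fit without MEF, the calls of Gsdmd, Rpph1, Map3k6 and Hist1h3e between iPSC and Stage2 ended. Their log2 fold changes were then 1.34, 0.83, 1.25 and 0.99. Ptgr1, a prostaglandin reductase gene, averaged 1.95 ± 0.557 CPM at Stage2, 44.7 ± 13.4 CPM in MEF and 8.72 ± 2.23 CPM in iPSC.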

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

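The test of genomic DNA was chosen only after the result was seen. Reads outside genes, which none of the comparisons uses, made up 42.8% of reads at Stage1, 49.9% at Stage2 and 38.8% in iPSC, against 9.21% in the MEF libraries. The same libraries had more genes with a count, on average 19875.7 ± 820.8 at Stage1, 19853.7 ± 517.2 at Stage2 and 19316.3 ± 782.6 in iPSC (SD, n = 3), against 14198.7 ± 384.5 in MEF.

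Depth did not account for the added genes. With every library thinned to the smallest gene total, the lowest sorted library still had 18083 genes with a count, and the highest MEF library had 14325. Scattered background reads remained a candidate explanation, since the excess nearly ended when a gene had to reach 1 CPM. The sorted mean was then 1.06 times the MEF mean, with 11944.3 ± 57.6 genes in MEF, 12013.3 ± 143 at Stage1, 12903 ± 143 at Stage2 and 12928 ± 211 in iPSC. Genomic DNA stayed open. On 1447 silent odorant, vomeronasal and taste receptor genes, the read density reached at most 20.4% of what the reads outside genes would need when estimated from genes without a read, but 28.6% to 57.6% when estimated from total reads, of which 3 genes held 33.3% to 40.8%. Sorting and cell state differed together between MEF and the other groups and could not be told apart here, so wider low-level transcription or unspliced RNA in pluripotent cells stays open too, as untested.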

How the results depend on the processing

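Library totals in place of TMM, leaving out structural RNA genes, a minimum of 5 CPM and the covariate were chosen only after the data were seen. Counts of called genes stayed within 1.5 times under RLE scaling, DESeq2, both other filters and the replicate block, in all 5 comparisons. With group names from the characteristics, Stage1 against MEF gave 3048 higher and 2921 lower, Stage2 against Stage1 1360 and 1310, iPSC against Stage2 5294 and 6636, and iPSC against Stage1 5372 and 6590. Genes above and below both end points were then 1154 and 326 at Stage1 and 1211 and 390 at Stage2. Progress was 13.6% and -3.63% at Stage1 (the latter reversed) and 13.0% and 0.623% at Stage2, for genes higher and lower in iPSC, 16 of 80 rule-named genes stayed called in their direction, and 68 of 160 list tests passed. These changes follow from the construction, which gives every library another group. A fold threshold of 2 left 774 genes lower for Stage2 against Stage1, 430 higher and 520 lower for iPSC against Stage2 and 857 lower for iPSC against Stage1, by construction. Without that threshold, genes outside both end points were 1580 above at Stage1 and 750 above and 581 below at Stage2. For iPSC against Stage2, a fit of only those groups gave 2307 higher and 2647 lower, the covariate 401 and 590, and library totals 882 higher, while library totals left 1678 lower for Stage2 against Stage1; the cause was not tested. Progress of genes higher in iPSC at Stage1 moved to 89.3% with a prior count of 0.5 and 93.0% with a threshold of 2-fold. At Stage2 it moved to 99.5% with RLE scaling, and that of genes lower in iPSC to 95.5% with RLE and 98.0% at 2-fold; the cause was not tested. List tests passed in 62 of 160 cases, in 0 with an estimated correlation, in 111 with directional and 152 with mixed fry. With the replicate block, 158 list tests passed or failed as before, 1 no longer passed and 1 newly passed. Estimated correlations widen the test, and fry asks whether a list moves at all. Leaving out 1 library gave 6414 to 6808 higher and 5102 to 5448 lower for Stage1 against MEF, 2367 to 2794 and 2115 to 2676 for Stage2 against Stage1, and 665 to 856 and 568 to 812 for iPSC against Stage2. It gave 2481 to 2914 and 1946 to 2303 for iPSC against Stage1, and 6587 to 6998 and 5091 to 5467 for iPSC against MEF. Genes above and below both end points ranged over 342 to 437 and 912 to 1052 at Stage1, and over 166 to 347 and 130 to 209 at Stage2. Progress ranged over 87.4% to 88.7% and 99.5% to 102.2% at Stage1, and over 98.0% to 99.1% and 96.3% to 97.0% at Stage2, and 78 to 80 rule-named genes kept their calls. Falls under this setting follow at least in part from the smaller number of libraries. Of single-gene checks on 208 gene and comparison pairs, 3222 kept direction and call, 24 lost and 7 gained a call, and 0 reversed. Replicate numbers as a block called 11774, 5799, 2425, 5660 and 11847 genes in the order of the comparisons, with 11715, 5696, 2342, 5551 and 11790 shared. With group names from the characteristics, gene and list calls were run only as the counts given here, not gene by gene or list by list. Depth limits calls of genes near the floor of 0.158 to 0.336 CPM.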

Other observations

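The tests of carried-over fibroblasts, of background reads on fibroblast genes and of Y-linked genes were chosen only after the results were seen, and the counts over other splits of the libraries were planned. Imprinted genes, which are expressed from the allele of a single parent, moved both ways between Stage1 and iPSC. Of 20 outside the Dlk1-Dio3 cluster, 5 were higher in iPSC, 8 lower and 7 not called (6 and 8 adjusted over the list alone), with adjusted p = 0.473 by camera and Benjamini-Hochberg. The growth restrictors Phlda2 and Cdkn1c rose with log2 fold changes of 3.37 and 3.03, and Peg10, Plagl1 and Grb10 fell with -2.60, -3.17 and -1.53. In the Dlk1-Dio3 cluster, whose Meg3 and Rian transcripts are read in mouse iPSC as marks of normal imprinting, 5 of 6 genes were lower in iPSC than in MEF and 1 was higher, also over the list alone, with adjusted p = 0.117 by camera and Benjamini-Hochberg. Meg3 averaged 80.04 ± 13 CPM in iPSC and 149.4 ± 12.6 CPM in MEF (SD, n = 3), and Rian 407 ± 59.8 and 1612 ± 437 CPM.

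Of 19 Polycomb genes 5 were higher in iPSC than at Stage1, 3 lower and 11 not called (6 and 3 over the list alone), with adjusted p = 0.817 by camera and Benjamini-Hochberg. Cbx2 rose with a log2 fold change of 1.29, and Bmi1 fell with -1.22. Of 12 WNT targets 4 were higher at Stage2 than at Stage1, 2 lower and 6 not called, also over the list alone, with adjusted p = 0.313 by camera and Benjamini-Hochberg. In iPSC against Stage2, 3 were lower, 1 higher and 8 not called (5 and 1 over the list alone), at camera adjusted p = 0.0473 with Benjamini-Hochberg and adjusted p = 0.222 with an estimated correlation. Lef1, a transcription factor of the pathway, rose from 1.94 ± 1.65 to 68.8 ± 11.9 CPM and fell to 10.1 ± 1.35 CPM in iPSC. Of 9 extraembryonic endoderm genes 5 were higher in iPSC than at Stage1 and 4 not called (5 higher and 1 lower over the list alone), at camera adjusted p = 0.0448 with Benjamini-Hochberg and adjusted p = 0.362 with an estimated correlation. Lamb1, a laminin of basement membranes, rose from 35.5 ± 11.4 to 163.4 ± 4.76 CPM.

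Sex-linked transcripts differed within the MEF and Stage1 groups, given here as CPM of gene totals without TMM. Xist, expressed from the inactive X chromosome, stood at 203.0 CPM in MEF replicate 1 and at 0.220 and 0 CPM in MEF replicates 2 and 3, and Ddx3y at 0.673 CPM against 104.3 and 111.1 CPM. Y-linked Eif2s3y stood at 0.112 CPM against 55.2 and 34.9 CPM, and Uty at 0.561 CPM against 53.5 and 39.0 CPM. These levels argue against a single animal as the source of all 3 MEF libraries. All 9 sorted libraries had Ddx3y reads, between 115.7 and 255.7 CPM. Reads on Xist, which cannot be told from those of its antisense partner Tsix here, stood at 3.195 CPM in Stage1 replicate 1 and at 36.6 and 50.7 CPM in replicates 2 and 3, and between 3.46 and 10.6 CPM in the Stage2 and iPSC libraries.

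The fibroblast list was higher at Stage2 than at Stage1, with a median fold of 3.70 and a lower quartile of 2.22 over its 27 genes (1.16 for silent receptor genes, and up to 2.29 between 2 libraries, so folds alone decided nothing), and, to a lesser degree, higher in iPSC than at Stage1. Background reads as the whole cause were argued against, since the 27 genes rose at Stage2 by a median of 4.27 CPM per kb of coding sequence (lower quartile 1.36), and the silent receptor genes held at most 0.171 CPM per kb in any sorted library. Carried-over fibroblasts like the MEF libraries, which the sort for Oct4-GFP should remove, would raise every abundant MEF transcript by the same percent of its MEF level. The 32 transcripts taken had at least 1000 CPM in MEF and below 1% of that level at Stage1, and 12 were in the fibroblast list. They were thus chosen in part on the Stage1 level from which the rise was measured. At Stage2, 71.9% rose within 2-fold of their median of 0.551%. Lgals1 at 5196 CPM in MEF changed by -0.118%, S100a11 by 0.0308% and Col12a1 by 1.86%. In iPSC, 50% lay within 2-fold of the median of 0.212%. A small share of such cells may add to the rise at Stage2, although Lgals1 showed no such rise, with 31.6 ± 8.77 CPM at Stage1 and 25.5 ± 3.33 CPM at Stage2, and transcription in the sorted cells themselves stays open, as untested.

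The Y-linked genes of at least 5 CPM at Stage2 kept unequal shares of that level in iPSC. Loss of the whole Y chromosome from a share of the cells was argued against as the whole cause. The largest share was 16.2 times the smallest, with Uty at 66.5% and Kdm5d at 4.10%. A deletion of neighbouring genes was argued against as the whole cause too. The 3 genes that kept over 0.4 of their level (Eif2s3y, Uty and Ddx3y) lie between Kdm5d and Usp9y, which fell below 0.2 of theirs. Zfy1 and Uba1y did so too, at 4.66% and 13.6%. Against Stage1, where Zfy1, Uba1y and Usp9y averaged 4.20, 2.12 and 2.91 CPM before 27.6, 9.27 and 6.80 CPM at Stage2, iPSC kept 30.7%, 59.5% and 14.5% of them and 2.51% of Kdm5d, so much of the fall of Zfy1 and Uba1y followed a rise at Stage2, while the 3 genes between Kdm5d and Usp9y kept 47.4% to 77.4% and the largest share was 30.9 times the smallest. Loss of the Y chromosome from a share of the cells as a part of the cause stays open, as untested. So do regulation of single Y-linked genes, separate deletions and a different parental line of the iPSC.

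Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. The real split called 11870 genes for Stage1 against MEF, 5969 for Stage2 against Stage1, 2670 for iPSC against Stage2, 5820 for iPSC against Stage1 and 11930 for iPSC against MEF, and the highest of the other splits called 0 in each, so that 1 of 10 gave as many. These gene counts decided nothing either. Each other split mixes libraries of both groups, whose difference then enters the spread and nearly ensures 0 calls. All these fits held the 12 libraries, with only the 6 of the comparison regrouped. Gene lists were here adjusted over the lists of 1 comparison alone. The real split called 13, 10, 17, 6 and 14 lists in the same order. The highest of the other splits called 16, 11, 14, 8 and 15, so that 6, 2, 1, 5 and 4 of 10 gave as many. For genes outside both end points, 100 regroupings of the 12 libraries were drawn, and their count decided nothing, since 98 of the 99 others spread the MEF libraries over several groups, whose spread then left 0 calls. The 403 and 1031 genes at Stage1 were reached by 1 of 100, with 0 as the highest other. The 264 and 192 genes at Stage2 were reached by 2 of 100, and the other grouping gave 3628 and 4832 genes. It put the 3 MEF libraries together in the place of Stage2, so it points to the distance of MEF from all other libraries.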
